A study of Arabidopsis thaliana with 18 samples.

How the data were processed

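Whole plants of Arabidopsis thaliana, aged 9 days, gave poly(A) RNA for 18 libraries, per the labels' protocols, with 3 libraries in each of 6 groups. The groups are WT and gemin2 at 22 °C, after 1 h and after 24 h at 10 °C. The deposited count tables give, for each library, the count of reads per gene, per intron and per alternative splicing bin. Per the submitters' processing notes the authors aligned the reads with TopHat2 2.0.9 to TAIR10 and worked in R 3.0.2 with edgeR 3.4.2, and the program that counted the reads and its use of strand are not given in the sources used here. The library kit named in the labels does not mark strand, so overlapping and antisense genes are reported as uncertain. The deposited tables of comparisons hold the authors' log2 fold changes of the features they list and the authors' p-values, given as false discovery rates (FDR). They were only set beside the results here.

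The tables' columns carry library letters A, B and C within each group. The labels give replicates 1, 2 and 3, which no source used here ties to the letters, so each column was assigned to its group and libraries are named by letter. The count tables hold 33602 genes, 120717 introns and 7973 alternative splicing bins. Of 120457 introns matched to a gene strand, 98.67% had GT and AG ends in the TAIR10 sequence held here, so the positions belong to that build. Library totals ran from 15675913 to 53766089 gene counts. The first 3 principal components of gene levels hold 50.05%, 16.56% and 10.24% of the variance, and all 18 libraries were kept.

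Counts of genes were scaled with TMM factors and filtered with edgeR's filterByExpr. Counts of introns and bins were tested against the count of their own gene, which entered as an offset. An intron or bin was tested if its mean was at least 10 counts and its gene had a mean of at least 50 counts and at least 10 in every library. The tests were edgeR's quasi-likelihood tests over 6 groups (edgeR 4.0.16, limma 3.58.1, R 4.3.3), for gemin2 against WT in each of the 3 conditions, for cold against 22 °C within each genotype, and for the genotype by cold interactions. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and an SE was derived from the change and its F statistic. Levels are CPM scaled by TMM, and region levels are percent of the gene's count. Of 187089 intron-library pairs with 10 or more intron counts, 1206 had an intron count above the gene count. These percents are therefore ratios of 2 counts and not strictly parts of the gene's reads. The share of intron reads was compared with an exact permutation test, two-sided, with genotypes permuted within conditions. Floors are 3 counts, and floors cover counting error only.

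The comparisons, tests, alternatives, gene lists and naming rule were fixed before the data were examined. The 18 lists cover cold and CBF genes, the clock, early calcium, touch and stress genes, flavonoids and anthocyanins, flowering, heat shock, ABA response, jasmonate, salicylic acid and defence, photosynthesis, ribosome biogenesis, Sm, LSm and snRNP genes, SR and hnRNP genes, reference genes, and markers of roots, dividing tissue, floral organs and seed maturation. Each list was tested with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation. GEMIN2 was named first. For each comparison of genes the rule named the 8 largest rises and 8 largest falls past the threshold, with a mean of at least 5 CPM and no overlap between the libraries of the groups (chance gives 10% of genes no overlap), and up to 3 members of each list with the smallest adjusted p. For the interactions it named the 5 smallest adjusted p-values in each direction. For introns and bins it named the 6 largest rises and falls with a mean of at least 20 counts and no overlap, every called region in a clock gene, and up to 3 each in the cold, flowering, snRNP and SR lists. The text leaves out some named features for length and says where it adds others.

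The alternatives were DESeq2 1.42.0, RLE factors, no filter or a mean of 3 counts for regions, no host gene offset, an absolute log2 change of at least 1, only the compared groups in the fit, a replicate block and each library left out in turn. Removing rRNA genes, and leaving out libraries for the correlations across introns, were added after the data were seen, as were the tests of other splits and of splice sites. The tests were tried on simulated data with 200 changed features. For genes edgeR recovered 50.7%, 75.4% and 95.7% of changes of 1.5, 2 and 4 times, for the interaction 14.5%, 55.7% and 82.9%, for introns 1.39%, 21.7% and 89.7%, and for bins 7.35%, 48.3% and 98.6%. Changed features were drawn from those with a mean of at least 20 counts. Simulated introns and bins all had the same fixed spread between libraries, whereas genes had the spread fitted to these data. Under these settings small changes of introns were mostly not detected at this depth and number of libraries. The rates for introns and bins in the real data may differ.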

Results

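The RNA of whole Arabidopsis thaliana seedlings was sequenced in 18 libraries, which per the labels fall into 6 groups of 3. Wild type plants of the Col ecotype (WT) and plants of the gemin2 mutant grew for 9 days in continuous white light at 22 °C. For each genotype, 1 group stayed at 22 °C and the other groups spent the last 1 h or 24 h at 10 °C. GEMIN2 encodes a protein that takes part in assembling the Sm ring of the spliceosomal small nuclear ribonucleoproteins (snRNPs). The libraries held between 15675913 and 53766089 counts over genes. Library C of gemin2 at 22 °C stood apart, with 22.5% of its counts in ribosomal RNA (rRNA) genes and 17.55% in chloroplast genes. In the other 17 libraries these shares ran from 0.367% to 4.06% and from 0.232% to 3.17%. By a chi-square per gene between libraries, which grows with depth, library A of gemin2 lay apart from B and C in the cold. After 1 h the values were 75.66 and 59.78, against 8.339 between B and C. After 24 h they were 44.85 and 38.72, against 10.21. Library A of WT lay apart after 24 h too, at 34.78 and 19.52 against 8.76 between B and C. Log2 changes are given ± standard error (SE) from 3 libraries per group, levels as mean ± SD (n = 3) in CPM (counts scaled to the size of the library), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether replicates were separate plantings, so p-values measure only the spread between samples.

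GEMIN2 (AT1G54380) was lower in all gemin2 libraries than in any WT library. At 22 °C it stood at 14.7 ± 1.41 CPM in WT and 4.204 ± 0.559 CPM in gemin2, a log2 change of -1.81 ± 0.12 (adjusted p = 3.14e-09). After 1 h at 10 °C the levels were 11.1 ± 0.748 and 2.98 ± 0.153 CPM, and after 24 h they were 21.1 ± 0.477 and 5.30 ± 0.449 CPM. Between the genotypes the cold response of GEMIN2 did not differ past the threshold (interaction -0.09 ± 0.17 at 1 h, adjusted p = 0.876, and -0.18 ± 0.17 at 24 h, adjusted p = 0.546). Reads in intron I003 of GEMIN2 (AT1G54380, chromosome 1, 20299245 to 20300121) made up 5.78 ± 3.22% of the gene's reads in WT at 22 °C and a larger share in gemin2 (1.32 ± 0.40, adjusted p = 0.0472). That call was lost without library A or B of WT (adjusted p = 0.107 and 0.179), without library A, B or C of gemin2 (adjusted p = 0.138, 0.102 and 0.1), and in 2 other settings. After 24 h the share was higher as well (1.92 ± 0.41, adjusted p = 8.10e-04). The intron's own log2 change, without the host gene's reads in the model, turned to -0.4997 at 22 °C and -0.06339 after 24 h and did not pass (edgeR adjusted p = 0.516 and 0.94), so the larger share goes with fewer reads of the gene. All positions are in the TAIR10 build that the deposited tables use.

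**Figure D1:**
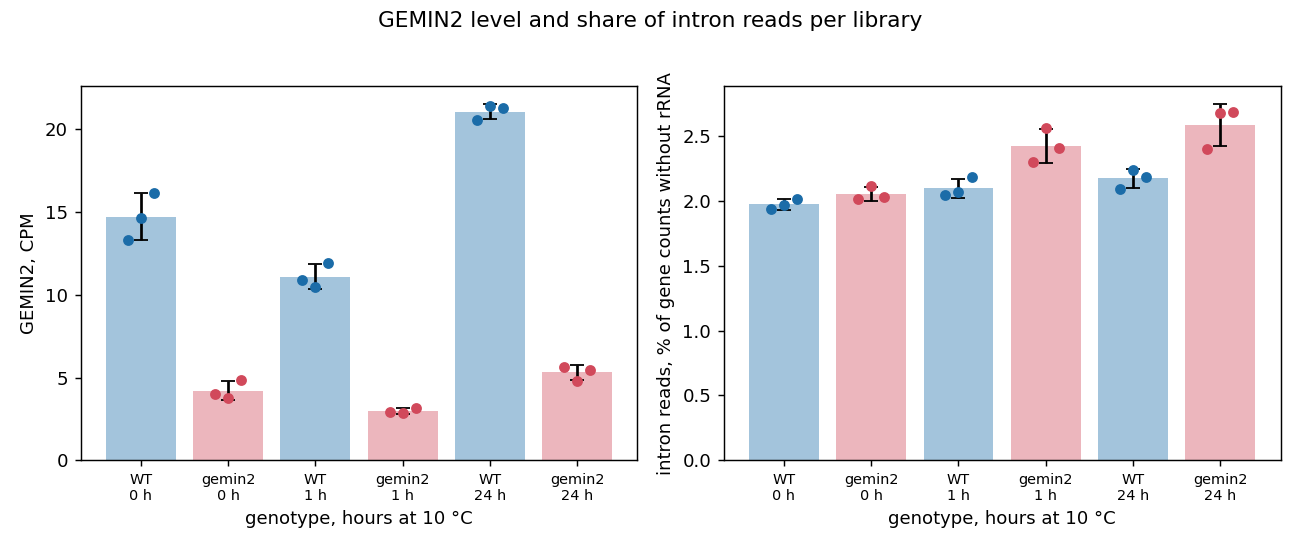
The left panel plots GEMIN2 in CPM and the right panel the reads in introns as a percent of gene counts with ribosomal RNA genes left out, for each of the 18 libraries in 6 groups. Points are libraries, bars are group means with SD (n = 3), and the gemin2 groups have GEMIN2 means of 4.204, 2.98 and 5.30 CPM against 14.7, 11.1 and 21.1 CPM in WT.

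The comparison of gemin2 with WT at 22 °C sets the genotypes side by side without cold. The morning genes of the circadian clock, LHY (AT1G01060) and CCA1 (AT2G46830), were lower in the mutant (-1.81 ± 0.12 and -1.54 ± 0.12), and the day-phased clock gene PRR7 (AT5G02810) was higher (1.48 ± 0.11). Transcripts of 9 of 13 flavonoid and anthocyanin genes and of FLC (AT5G10140), a repressor of flowering, were lower, and SOC1 (AT2G45660), a promoter of flowering, was higher. LHY fell from 123 ± 11.9 to 35.3 ± 5.19 CPM. Of 21918 genes tested, 2308 were higher and 2228 lower in gemin2.

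Of the 22 clock genes of a fixed list, 9 rose and 4 fell over all genes tested, and 10 rose and 4 fell adjusted over the list alone. Grouped after the results were seen, 8 morning genes had a median of -0.411 and 10 day or evening genes one of 0.781. The labels give no harvest hours, so a different clock phase cannot be told from a different hour of harvest. Of 13 flavonoid and anthocyanin genes none rose and 9 fell (10 adjusted over the list alone), among them the regulators PAP1 (AT1G56650) (-2.06 ± 0.18) and TT8 (AT4G09820) (-3.08 ± 0.35) and the enzymes DFR (AT5G42800) (-2.53 ± 0.33) and LDOX (AT4G22880) (-2.32 ± 0.26). The list as a set was lower with camera's preset correlation (adjusted p = 8.51e-13), and not with an estimated correlation (adjusted p = 0.118). UF3GT (AT5G54060), an enzyme that adds a sugar to anthocyanins, fell with them (-2.44 ± 0.48), a call that was lost in some setting. The glutathione transferase ATGSTF12 (AT5G17220) fell too (-3.05 ± 0.46). Of 15 flowering genes measured, 3 rose and 5 fell, with FLC at -3.35 ± 0.41, AGL24 (AT4G24540) at -1.70 ± 0.22 and SOC1 at 1.255 ± 0.14, and the same counts held adjusted over the list alone. FLC stood at 1.81 ± 0.589 CPM in WT and 0.174 ± 0.0276 CPM in gemin2.

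Of the 21 genes of the cold list, which holds the CBF factors and cold-regulated (COR) genes, 7 rose and 1 fell without cold (8 and 1 adjusted over the list alone). KIN2 (AT5G15970) and KIN1 (AT5G15960) rose (1.03 ± 0.12 and 0.93 ± 0.14), and ADH1 (AT1G77120), which another annotated gene overlaps, fell (-1.93 ± 0.28). Of 11 early calcium, touch and stress genes 4 rose over all genes and over the list alone, among them the calcium sensor gene TCH3 (AT2G41100) (0.93 ± 0.13) and ERF5 (AT5G47230) (0.87 ± 0.21). Both lists passed as sets with the preset correlation (adjusted p = 0.00462 and 0.0355) and not with an estimated one (adjusted p = 0.480 and 0.511). Of 21 nuclear photosynthesis genes 6 fell and none rose, over all genes and over the list alone, with the Rubisco small subunit gene RBCS2B (AT5G38420) at -1.12 ± 0.19 and Rubisco activase, RCA (AT2G39730), at -0.93 ± 0.17 (adjusted p of the list 0.0106, and adjusted p = 0.640 with an estimated correlation). Of 33 Sm, LSm and other snRNP genes 5 rose and 2 fell, GEMIN2 included (6 and 2 adjusted over the list alone). STA1 (AT4G03430), a pre-mRNA splicing factor, rose (0.52 ± 0.10), and so did the Sm core gene SMD1A (AT3G07590) (0.80 ± 0.11), which overlaps another gene.

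Among salicylic acid and defence genes, 2 of 13 rose and 1 fell (4 and 1 adjusted over the list alone), with FMO1 (AT1G19250) at 2.54 ± 0.43 and CBP60G (AT5G26920) at 1.62 ± 0.29. The nitrate transporter gene ATNRT2.1 (AT1G08090) fell (-3.48 ± 0.83), from 43 counts over the WT libraries to 6 over those of gemin2, both below 1 CPM. LHCB4.3 (AT2G40100), a light-harvesting gene, fell as well (-2.75 ± 0.43). AT2G04135 had no count in the 3 WT libraries and 380 counts in the gemin2 libraries (4.22 ± 0.918 CPM), and AT4G04223 rose by 3.83 ± 0.18. The chloroplast genes PSBA (ATCG00020) and PSBD (ATCG00270) and 4 chloroplast rRNA genes were among the 8 largest rises (PSBA 4.40 ± 0.93, 179.5 ± 241 CPM in gemin2), and library C of gemin2, which is rich in these RNAs, sets their mean. With 3 libraries per group the smallest p of a permutation over libraries is 0.1, so single genes rest on the model's shared spread.

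**Figure D2:**
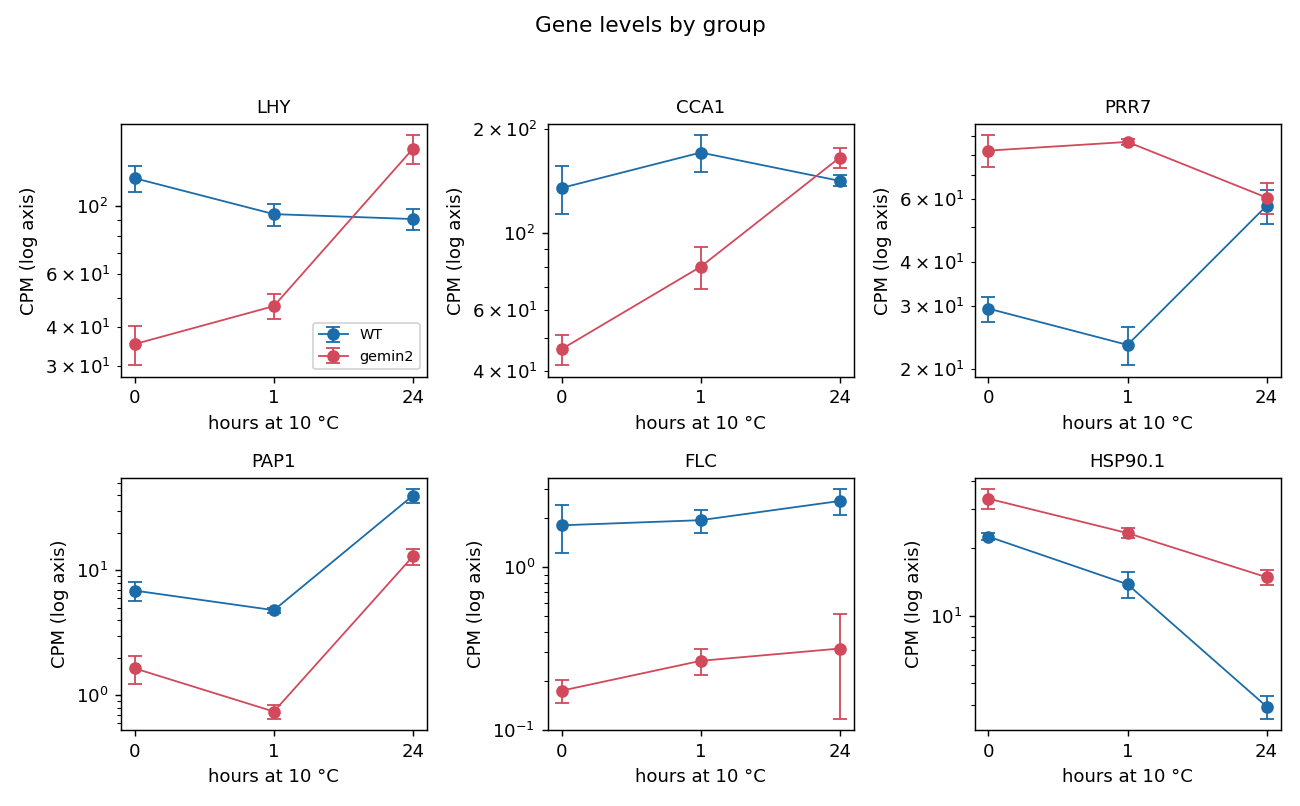
Each panel plots the level of 1 gene in CPM on a log axis in the 6 groups, with points for group means and bars for SD (n = 3), WT and gemin2 in separate colours and the hours at 10 °C on the x axis. LHY lies below WT in gemin2 at 0 and 1 h, at 35.3 against 123 CPM at 0 h, and above it at 24 h, at 154 against 90.7 CPM.

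Introns were tested against the reads of their own gene, so a rise means more intron reads per gene read. A percent of the gene's reads is the intron count over the gene count, a ratio that can exceed 100%. At 22 °C, 380 of 9366 introns had more reads in gemin2 and 92 had fewer. The median log2 change over all tested introns was 0.0929. Intron I010 of XCT (AT2G21150, chromosome 2, 9067620 to 9067712), a gene with a role in the clock, went from 0.0513 ± 0.0888% of the gene's reads to 3.95 ± 0.933% (log2 change 6.06 ± 0.77, adjusted p = 3.21e-06). Intron I002 of ATBPM2 (AT3G06190, chromosome 3, 1874759 to 1874855) (4.18 ± 0.65), intron I001 of ATCRT1 (AT5G56340, chromosome 5, 22817758 to 22818220) (4.86 ± 0.85) and intron I001 of AT4G14230 (chromosome 4, 8200943 to 8201019) (4.89 ± 0.77) rose as well. In WT each of these 4 introns held at most 0.168% of its gene's reads.

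Of the clock list, intron I007 of PRR9 (AT2G46790, chromosome 2, 19234710 to 19234802) rose from 1.12 ± 1.07% to 10.5 ± 0.631%, and intron I004 of TOC1 (AT5G61380, chromosome 5, 24676740 to 24676823) rose by 2.36 ± 0.45. Intron I004 of CCA1 (AT2G46830, chromosome 2, 19246385 to 19246751) fell from 3.96 ± 0.379% to 1.53 ± 0.241%. Intron I010 of SR30 (AT1G09140, chromosome 1, 2945303 to 2945381), in a gene of an SR splicing factor, rose by 2.28 ± 0.40, and intron I012 of SR34B (AT4G02430, chromosome 4, 1070887 to 1071273) fell by 1.52 on the log2 scale. Intron I002 of LSM1B (AT3G14080, chromosome 3, 4667778 to 4668380) rose by 2.25 ± 0.61, a call that was lost in some setting. Intron I004 of AT5G41750 held 0 reads among 71 gene counts over the 3 WT libraries, which allows a share of up to 4.23% (counting error only), and 10.4 ± 2.23% in gemin2. Its call, too, was lost in some setting. Without the host gene's reads in the model, 501 introns were higher and 316 lower.

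Annotated alternative splicing bins, which the deposited tables class by event, showed 71 rises and 35 falls among 3809 tested at 22 °C. The fall with the smallest adjusted p was that of bin E005 of U1-70K (AT3G50670, chromosome 3, 18827440 to 18828348), a retained intron of the gene for a U1 snRNP protein, from 4.39 ± 0.297% to 0.286 ± 0.0595% (-3.93 ± 0.22, adjusted p = 1.47e-12). Retained-intron bins gave 28 rises and 12 falls, bins of alternative 5' sites 16 and 1, and bins of alternative 3' sites 4 and 6. Bin E002 of ATBBD1 (AT1G75380, chromosome 1, 28281709 to 28281783) (3.81 ± 0.35), bin E010 of iPGAM2 (AT3G08590, chromosome 3, 2611240 to 2611329) (4.66 ± 0.48) and bin E005 of RPS5A (AT3G11940, chromosome 3, 3779357 to 3779441) (2.91 ± 0.26), in a ribosomal protein gene, were retained introns that rose. Without library A or C of gemin2 at 22 °C, 64 or 69 bins passed in place of 106, and without the host gene's reads in the model 185 rose and 193 fell.

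**Figure D3:**
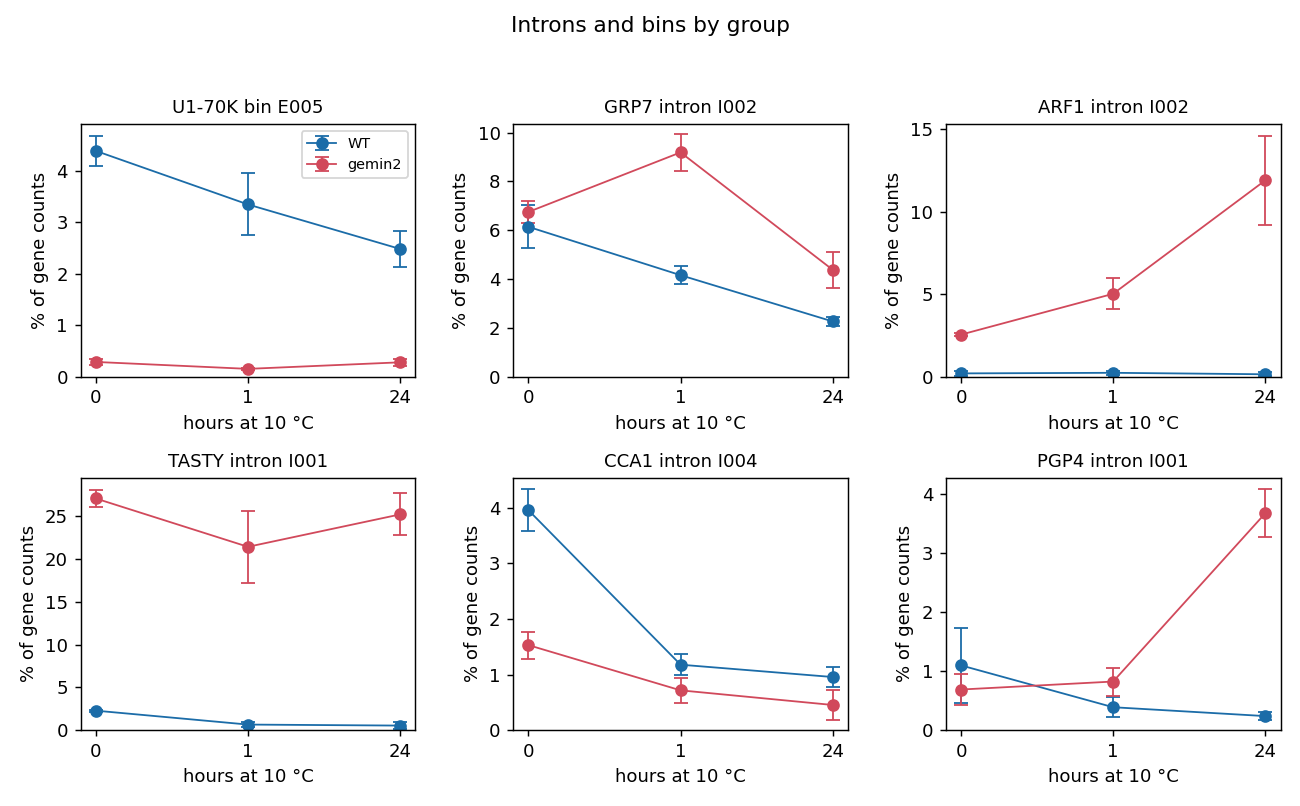
Each panel plots reads in 1 intron or alternative splicing bin as a percent of the reads of its gene in the 6 groups, with points for group means and bars for SD (n = 3), WT and gemin2 in separate colours and the hours at 10 °C on the x axis. Bin E005 of U1-70K lies at 4.39%, 3.35% and 2.48% in WT and at 0.286%, 0.151% and 0.279% in gemin2.

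After 1 h at 10 °C the genotypes were compared again, to see which differences stand beside an early cold response. Anthocyanin genes were lower in gemin2 at this time too, and so were CO (AT5G15840), a promoter of flowering, and FLC. PRR7 and the evening clock gene GI (AT1G22770) were higher, and so were 5 of 9 heat shock genes. The number of introns with more reads in gemin2 was 1141, against 160 with fewer. Over all tested introns the median log2 change was 0.235, so a shift shared by many introns was not told apart from changes of single ones. Of the genes, 3637 were higher and 3823 lower.

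All 13 flavonoid and anthocyanin genes fell, over all genes and adjusted over the list alone, with PAP1 at -2.68 ± 0.20 and TT8 at -2.25 ± 0.30 (adjusted p of the list 4.35e-11, and adjusted p = 0.157 with an estimated correlation). Of the clock list 11 rose and 5 fell (11 and 6 adjusted over the list alone), with PRR7 at 1.89 ± 0.11, GI at 1.22 ± 0.11 and CCA1 at -1.09 ± 0.12. Of the flowering list 3 rose and 7 fell (3 and 8 adjusted over the list alone), with CO at -2.44 ± 0.15, FLC at -2.87 ± 0.36 and SOC1 at 1.15 ± 0.14. These lists passed with the preset correlation (adjusted p = 0.0316 and 0.0387) and neither with an estimated one (adjusted p = 0.246 and 0.189). Of 9 heat shock genes measured 5 rose, over all genes and over the list alone, with the chaperone gene HSP90.1 (AT5G52640) at 0.75 ± 0.11 and the heat shock factor gene HSFA2 (AT2G26150) at 1.95 ± 0.51, and the list as a set did not pass (adjusted p = 0.0535). Of 25 SR and hnRNP genes 2 rose and 9 fell (3 and 11 adjusted over the list alone), with RS2Z32 (AT3G53500) at -0.53 ± 0.11, and again the set did not pass (adjusted p = 0.0798). Of the snRNP list 15 rose and 2 fell, over all genes and over the list alone.

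Of the cold list 8 rose and 3 fell, over all genes and over the list alone, with COR413PM1 (AT2G15970) at 0.94 ± 0.10 and KIN2 at 0.89 ± 0.12. Of the early calcium, touch and stress list 7 rose and 1 fell, by both counts, with ERF5 at 1.37 ± 0.17. Both passed with the preset correlation (adjusted p = 0.0316 and 0.00681) and not with an estimated one (both adjusted p = 0.289). Rubisco genes were lower (RBCS2B -1.66 ± 0.19, RBCS1B (AT5G38430) -1.17 ± 0.16) within a photosynthesis list of which 4 rose and 6 fell by both counts. Of the 13 defence genes 5 rose and 1 fell (6 and 1 adjusted over the list alone). Among them the pathogenesis gene PR1 (AT2G14610) was higher by 7.34 ± 1.39, at 7.745 ± 3.38 CPM in gemin2. WT held only 4 counts of it over its 3 libraries (0.0388 ± 0.0671 CPM), so the size of this change is uncertain. The MATE transporter family member AT2G04050 rose by 3.07 ± 0.30 and AT2G18190 by 3.60 ± 0.46. Of 12 root markers 1 rose and 6 fell (1 and 7 adjusted over the list alone), with RHD6 (AT1G66470) at -1.35 ± 0.25 and SHR (AT4G37650) at -0.73 ± 0.14, and the list passed with the preset correlation (adjusted p = 0.0316) and not with an estimated one (adjusted p = 0.372).

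Among introns, intron I001 of TASTY (AT1G54040, chromosome 1, 20171988 to 20173852) went from 0.663 ± 0.282% in WT to 21.4 ± 4.24% in gemin2 (4.99 ± 0.24), and intron I002 of ARF1 (AT1G59750, chromosome 1, 21979620 to 21980383), in an auxin response factor gene, from 0.233 ± 0.106% to 5.02 ± 0.940% (4.38 ± 0.36). Intron I001 of WRKY33 (AT2G38470, chromosome 2, 16108719 to 16108967), in a stress-responsive factor gene, rose by 4.71 ± 0.51. Of the clock list, intron I001 of TOC1 (AT5G61380, chromosome 5, 24675673 to 24675989) rose by 2.51 ± 0.37 and intron I001 of PRR5 (AT5G24470, chromosome 5, 8356297 to 8356380) by 1.45 ± 0.31. Intron I002 of GRP7 (AT2G21660, chromosome 2, 9265894 to 9266202), in the gene of an RNA-binding protein, rose by 1.14 ± 0.12. Of the alternative splicing bins 234 rose and 85 fell, 94 and 26 of them retained introns, and U1-70K bin E005 again fell (-4.46 ± 0.23). Intron I004 of AT3G06760 (chromosome 3, 2133422 to 2133540) fell by 2.42 on the log2 scale. The count of 319 bins rested on single libraries: it was 163 or 127 without library A or B of WT at 1 h, and 574, 120 or 144 without library A, B or C of gemin2 at 1 h. Without the host gene's reads in the model 1191 introns rose and 443 fell, and 325 bins rose and 247 fell.

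After 24 h at 10 °C 4 of 9 heat shock genes, 10 of 11 abscisic acid (ABA) response genes, 21 of 33 snRNP genes and 8 of 11 early calcium, touch and stress genes were higher in gemin2, and 8 of 13 flavonoid and anthocyanin genes were lower. These lists passed as sets with camera's preset correlation, and 0 of 18 lists passed with an estimated one. LHY, lower in gemin2 at 22 °C, was higher by 0.77 ± 0.11. HSP90.1 was higher by 1.90 ± 0.12 and HSP70 (AT3G12580) by 1.32 ± 0.13. Intron reads were higher in gemin2 for 1435 introns and lower for 152. Over all tested introns the median log2 change was 0.226, so here too a shared shift was not told apart from changes of single introns. Of the genes, 4722 were higher and 3991 lower.

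Of 11 ABA response genes 10 rose and none fell, over all genes and over the list alone, with the phosphatase genes HAB1 (AT1G72770) (0.66 ± 0.10) and HAI2 (AT1G07430) (1.47 ± 0.24), which act as negative regulators of ABA signalling (adjusted p of the list 0.00103, and adjusted p = 0.369 with an estimated correlation). Of 33 snRNP genes 21 rose and 2 fell (22 and 2 adjusted over the list alone), with STA1 at 1.27 ± 0.10 and SMD1A at 1.16 ± 0.11 (adjusted p of the list 0.00110, and adjusted p = 0.0757 with an estimated correlation). Of 9 heat shock genes 4 rose, by both counts, and of the early calcium, touch and stress list 8 rose and 1 fell, by both counts, with ERF105 (AT5G51190) at 1.46 ± 0.21 and WRKY33 (AT2G38470), which overlaps another gene, at 1.66 ± 0.14. These lists passed with the preset correlation (adjusted p = 0.00589 and 0.00110) and not with an estimated one (both adjusted p = 0.226). Of the flavonoid list 8 fell and none rose (10 adjusted over the list alone), with F3PH (AT5G07990) at -2.33 ± 0.32 (adjusted p of the list 1.63e-05, and adjusted p = 0.226 with an estimated correlation).

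Of the cold list 10 rose and 2 fell (12 and 2 adjusted over the list alone), with the dehydrin gene LTI30 (AT3G50970) at 1.46 ± 0.13 and ZAT12 (AT5G59820) at 1.81 ± 0.17. Of the clock list 11 rose and 1 fell (12 and 1 adjusted over the list alone), with RVE8 (AT3G09600) at 0.89 ± 0.13 and LNK1 (AT5G64170) at 0.72 ± 0.11. Of 12 ribosome biogenesis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with REIL2 (AT2G24500) at 0.63 ± 0.08. These 3 lists passed with the preset correlation (adjusted p = 0.0188, 0.0315 and 0.0315) and not with an estimated one (adjusted p = 0.350, 0.244 and 0.428). Of the flowering list 4 rose and 4 fell by both counts, with FLC at -2.95 ± 0.36, MAF2 (AT5G65050) at -0.91 ± 0.11 and SOC1 at 1.31 ± 0.14. Among single genes AGO3 (AT1G31290), an Argonaute gene, rose by 4.79 ± 0.23, AT2G18190 by 6.65 ± 0.19 and the cyclin gene CYCB1;1 (AT4G37490) by 1.80 ± 0.18. ICS1 (AT1G74710), which makes a salicylic acid precursor, rose by 1.31 ± 0.15 and ACD6 (AT4G14400) fell (-2.17 ± 0.31), among 5 rises and 1 fall in the defence list (6 and 1 adjusted over the list alone).

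Intron I002 of ARF1 held 11.9 ± 2.69% of the gene's reads in gemin2 against 0.143 ± 0.124% in WT (6.07 ± 0.37), and intron I001 of TASTY 25.2 ± 2.45% against 0.544 ± 0.423%. Intron I009 of RS40 (AT4G25500, chromosome 4, 13027130 to 13027209) (3.58 ± 0.41) and intron I007 of SCL30 (AT3G55460, chromosome 3, 20563315 to 20563399) (2.25 ± 0.29), in genes of SR splicing factors, rose. Intron I011 of AT1G13350 (chromosome 1, 4575996 to 4576238) fell (-3.85 ± 0.35). Of the clock list, introns of PRR5, TOC1, PRR9, LHY and PRR7 rose, with I001 of PRR5 at 2.99 ± 0.44, while introns I004 and I005 of CCA1 fell and I007 rose. Of these, the calls of the 3 CCA1 introns and of intron I004 of PRR7 were lost without single libraries at 24 h: A or B of either genotype for I004 of CCA1, A of either for I005, C of gemin2 for I007 and C of WT for PRR7. Of the bins 180 rose and 51 fell. U1-70K bin E005 fell (-3.13 ± 0.20), as did bin E009 of PRP39 (AT1G04080, chromosome 1, 1054285 to 1054385), a skipped exon of a U1 snRNP-associated factor gene (-3.85 ± 0.62), and bin E015 of LHY (AT1G01060, chromosome 1, 37399 to 37568) rose (1.67 ± 0.31). Without library A, B or C of gemin2 at 24 h, 397, 147 or 151 bins passed in place of 231, and without the host gene's reads in the model 517 bins rose and 285 fell.

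**Figure D4:**
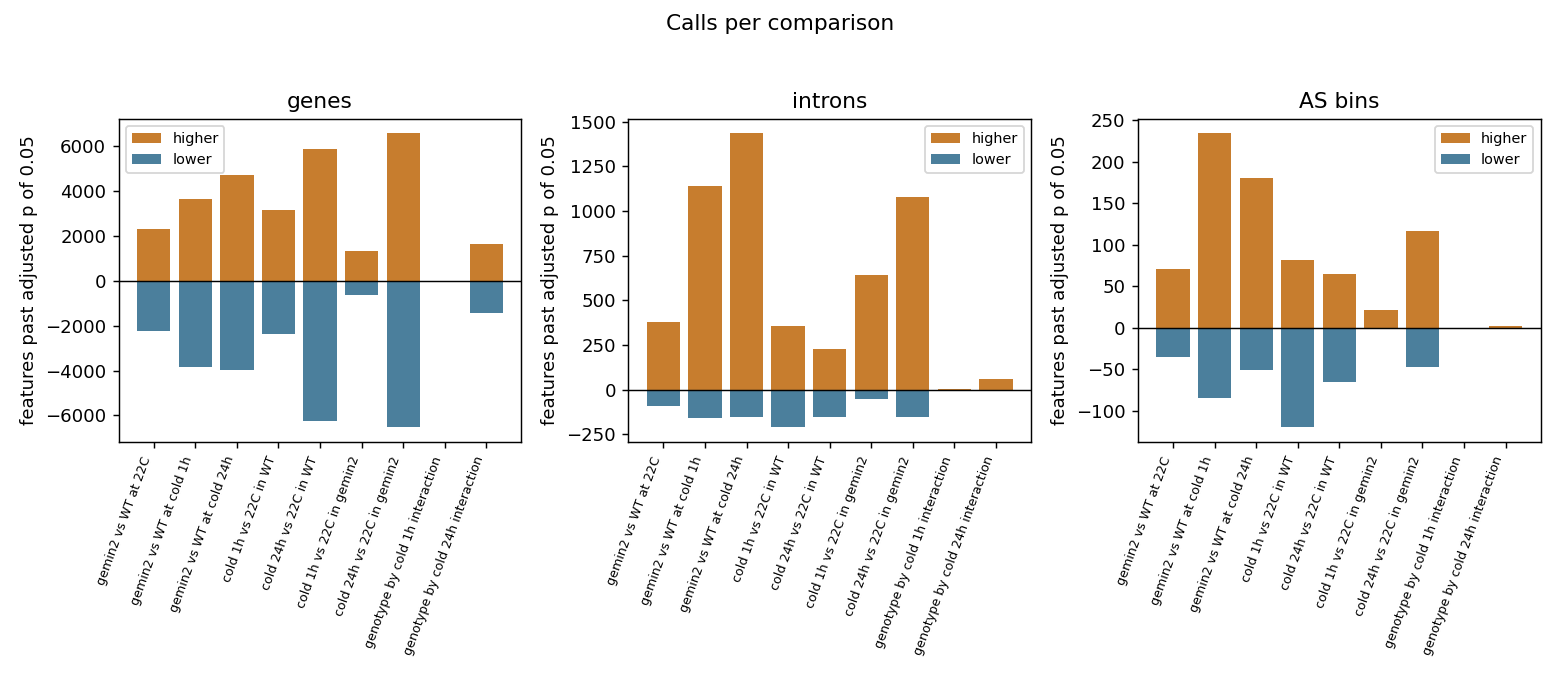
Bars give the number of genes, introns and alternative splicing bins past an adjusted p of 0.05 in each of the 9 comparisons, with higher features above 0 and lower features below 0. For introns the counts of higher features exceed those of lower ones in all 9 comparisons, by 1435 to 152 for gemin2 against WT at 24 h.

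The response to 1 h at 10 °C was measured within each genotype. In both, CBF2, at least 10 of 11 early calcium, touch and stress genes, PRR5 and CO rose within 1 h. CBF2 (AT4G25470), a transcription factor of the cold response, rose by 5.78 ± 0.62 in WT and 5.54 ± 0.52 in gemin2. The calcium sensor gene CML38 (AT1G76650) rose by 5.08 ± 0.41 and 4.71 ± 0.34, and the zinc finger gene ZAT10 (AT1G27730) by 5.02 ± 0.59 and 4.35 ± 0.56. In WT 3151 genes rose and 2348 fell, and in gemin2 1353 rose and 649 fell. These counts do not test a difference between the genotypes. The interaction at 1 h, which does, passed for 21 genes.

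Of 11 early calcium, touch and stress genes 10 rose in WT and 11 in gemin2, over all genes and over the list alone, with ERF105 at 4.07 ± 0.27 and 4.04 ± 0.23. Of the cold list 11 rose and 2 fell in WT (12 and 2 adjusted over the list alone) and 8 rose in gemin2 (10 adjusted over the list alone), with RAV1 (AT1G13260) at 2.84 ± 0.11 and 3.09 ± 0.11. Of 15 flowering genes 3 rose in WT and 2 in gemin2 by both counts, with CO at 3.96 ± 0.17 and 2.40 ± 0.18 and the repressor gene TEM1 (AT1G25560) at 3.06 ± 0.18 and 2.45 ± 0.17. These 3 lists passed in both genotypes, with an estimated correlation too (largest adjusted p = 0.0327). Of the clock list 11 rose and 5 fell in WT (13 and 5 adjusted over the list alone) and 9 rose and 1 fell in gemin2 (11 and 1 adjusted over the list alone), with PRR5 (AT5G24470) at 3.18 ± 0.16 and 3.05 ± 0.15. The clock list passed with an estimated correlation in gemin2 (adjusted p = 0.00651) and in WT with the preset one only (adjusted p = 0.00779, and adjusted p = 0.108 with an estimated correlation). Without harvest hours in the labels, an effect of the hour of day on clock genes cannot be told from that of cold.

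Heat shock genes fell: 5 of 9 in WT by both counts and 3 in gemin2 (4 adjusted over the list alone), with HSP70 at -1.19 ± 0.13 and -0.80 ± 0.13 (adjusted p of the list 0.00206 and 0.00568, and adjusted p = 0.0770 and 0.116 with an estimated correlation). Among single genes, LSU1 (AT3G49580), LSU2 (AT5G24660) and LSU3 (AT3G49570) fell by 3.09, 2.28 and 3.43 on the log2 scale in WT and by 2.97, 2.73 and 3.08 in gemin2. NCED3 (AT3G14440), an enzyme of ABA synthesis, rose (1.79 ± 0.22 and 1.36 ± 0.21) and HAI2 fell (-2.34 ± 0.28 and -1.92 ± 0.25). Of 10 jasmonate genes measured 2 rose in WT by both counts, JAZ1 (AT1G19180) (1.97 ± 0.24) and JAZ5 (AT1G17380) (2.50 ± 0.39). The defence regulator gene CBP60G rose in both genotypes (2.30 ± 0.28 and 1.64 ± 0.23). Without rRNA genes, a setting chosen after the data were seen, the WT calls split into 2677 higher and 3291 lower. Without library A or B of WT at 1 h, 3611 or 3623 genes passed in place of 5499.

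Intron reads rose for 357 introns and fell for 209 in WT, and for 643 and 52 in gemin2. The WT libraries at 22 °C held fewer counts than those of gemin2, so these numbers do not measure a difference between genotypes. Intron I002 of ELF3 (AT2G25930, chromosome 2, 11060837 to 11062016), in a clock gene, fell from 7.56 ± 2.28% to 0.968 ± 0.273% in WT and from 4.35 ± 0.745% to 1.81 ± 0.480% in gemin2. In gemin2 intron I002 of RVE2 (AT5G37260, chromosome 5, 14752106 to 14752236), a relative of CCA1, rose (3.39 ± 0.40) and its intron I004 fell (-1.34 ± 0.14), and intron I001 of COR15B (AT2G42530, chromosome 2, 17709420 to 17709676) rose (4.26 ± 0.46). In WT intron I005 of GRP8 (AT4G39260, chromosome 4, 18274568 to 18274850) fell (-1.02 ± 0.15), and so did bin E005 of RS40 (AT4G25500, chromosome 4, 13025600 to 13025856), a skipped exon (-2.06 ± 0.33). Bins gave 82 rises and 120 falls in WT and 21 rises and 1 fall in gemin2, where bins E003 and E004 of ERD15 were among the rises (2.69 ± 0.34 and 2.24 ± 0.27). Without library B or C of WT at 22 °C, or B of WT at 1 h, 357, 375 or 283 introns passed in WT in place of 566, and without library A, B or C of gemin2 at 22 °C, 426, 418 or 445 passed in gemin2 in place of 695. Bins in WT numbered 54 or 31 without library A or B of WT at 1 h, and 79 or 67 without B or C of WT at 22 °C, in place of 202, and in gemin2 13, 12 or 14 without A, B or C of gemin2 at 22 °C, and 11 without B of gemin2 at 1 h, in place of 22. Without the host gene's reads in the model 745 introns rose and 259 fell in WT, and bins gave 225 rises and 168 falls in WT and 117 and 21 in gemin2.

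The response to 24 h at 10 °C took in more genes than that to 1 h in each genotype. In each genotype 18 of 21 cold genes, all 12 ribosome biogenesis genes and at least 11 of 13 flavonoid and anthocyanin genes rose, and 19 of 21 nuclear photosynthesis genes fell. With an estimated correlation the cold and ribosome lists passed as sets and the flavonoid and photosynthesis lists did not. The chloroplast-protecting protein gene COR15A (AT2G42540) rose by 6.71 ± 0.26 in WT, GOLS3 (AT1G09350), an enzyme of galactinol synthesis, by 8.16 ± 0.50 and 7.17 ± 0.40 in WT and gemin2, and the chloroplast sugar-phosphate transporter gene GPT2 (AT1G61800) by 8.86 ± 0.35 and 7.91 ± 0.31. In WT 5882 genes rose and 6234 fell, and in gemin2 6581 rose and 6525 fell.

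Of the 21 cold genes 18 rose and 1 fell in each genotype, over all genes and over the list alone, with COR78 (AT5G52310) at 5.21 ± 0.19 and 5.44 ± 0.19, and KIN2 at 3.35 ± 0.13 and 2.92 ± 0.13. All 12 ribosome biogenesis genes rose in each genotype by both counts, with the fibrillarin gene FIB2 (AT4G25630), which overlaps another gene, at 2.88 ± 0.10 and 2.88 ± 0.10 and nucleolin, NUC1 (AT1G48920), at 2.50 ± 0.09 and 2.38 ± 0.09. Of 33 snRNP genes 26 rose in WT and 27 in gemin2 (26 rose and 1 fell, and 28 rose, adjusted over the list alone), with PRP8 (AT1G80070) at 0.95 ± 0.08 in gemin2. These 3 lists passed in both genotypes with an estimated correlation too (largest adjusted p = 0.0207). Of 21 photosynthesis genes 19 fell and none rose in each genotype by both counts, with LHCB3 (AT5G54270), which overlaps another gene, at -2.07 ± 0.10 and -1.80 ± 0.10 (adjusted p of the list 1.10e-11 and 3.39e-08, and adjusted p = 0.137 and 0.189 with an estimated correlation). Of 13 flavonoid genes 12 rose in WT, and 11 rose and 1 fell in gemin2 (12 and 1 adjusted over the list alone), with PAP1 at 2.52 ± 0.16 and 2.97 ± 0.18 (adjusted p of the list 6.27e-07 and 2.02e-06, and adjusted p = 0.137 and 0.189 with an estimated correlation).

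Of 25 SR and hnRNP genes 13 rose and 7 fell in WT and 15 rose and 5 fell in gemin2 (14 and 8, and 15 and 5, adjusted over the list alone), with GRP7 (AT2G21660) at 2.90 ± 0.13 and 1.59 ± 0.13, and neither set passed (adjusted p = 0.0986 and 0.123). Defence genes gave 6 rises and 2 falls in WT and 9 and 1 in gemin2 by both counts, with PR5 (AT1G75040) at 2.94 ± 0.22 and 2.69 ± 0.20 (adjusted p of the list 0.0117 and 0.0111, and adjusted p = 0.234 and 0.189 with an estimated correlation). In WT 7 of 11 ABA response genes fell and 1 rose by both counts, among them RAB18 (AT5G66400) (-4.15 ± 0.39) and HAB1 (-1.48 ± 0.10) (adjusted p of the list 0.0191, and adjusted p = 0.596 with an estimated correlation), and in gemin2 4 rose and 4 fell. Of 10 jasmonate genes 7 fell in gemin2 and none rose (8 adjusted over the list alone), with VSP2 (AT5G24770) at -5.41 ± 0.88, and 2 rose and 2 fell in WT (2 and 4 adjusted over the list alone). Library A of gemin2 at 22 °C stood above the others of its group in VSP2 (701 ± 933 CPM), and without it VSP2 changed by -3.30 and 6 of the 10 genes fell and 1 rose. HSP90.1 fell in both genotypes (-2.50 ± 0.12 and -1.16 ± 0.11). Further falls were those of ATFRO6 (AT5G49730), an iron reductase gene (-5.06 ± 0.18 and -6.17 ± 0.20), and of GASA6 (AT1G74670) (-5.14 ± 0.26 and -6.76 ± 0.29).

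Intron reads rose for 228 introns and fell for 150 in WT, and for 1081 and 153 in gemin2. As at 1 h, the lower depth of WT at 22 °C limits a comparison of these numbers between genotypes. Intron I002 of GRP7 fell in WT against the rising reads of its gene (-1.44 ± 0.12), and rose without the host gene's reads in the model (1.47). Intron I004 of CCA1 fell in both genotypes (-2.05 ± 0.27 and -1.70 ± 0.34), and its log2 change in gemin2 was 0.11 without the host gene's reads in the model. Intron I004 of RVE8 (AT3G09600, chromosome 3, 2947404 to 2947521) rose in both genotypes (2.30 ± 0.56 and 4.17 ± 0.82). It went from 0.634% to 3.24% in WT and from 0.0968% to 2.02% in gemin2, where it held 2 reads at 22 °C. In gemin2 intron I001 of RCD1 (AT1G32230, chromosome 1, 11612369 to 11612737) rose (3.44 ± 0.33). Intron I002 of COR15A held no read in WT at 22 °C and 1.36 ± 0.0428% of the gene's reads at 24 h. Bin E005 of RS40 fell in both genotypes (-2.86 ± 0.32 and -2.52 ± 0.31), as did bin E021 of AGO1 (AT1G48410, chromosome 1, 17890644 to 17890649), an alternative 3' site of an Argonaute gene (-2.002 ± 0.44 and -2.67 ± 0.43). The call of the AGO1 bin in WT was lost in some setting. Bins gave 64 rises and 66 falls in WT and 116 and 48 in gemin2. With only the WT groups compared in the fit, 177 introns and 54 bins passed in WT, and without library B of WT at 24 h 218 introns passed. Bins in WT numbered 78 or 81 without B or C of WT at 22 °C, and 85 or 77 without B or C of WT at 24 h, in place of 130. In gemin2 they numbered 92 or 105 without A or C of gemin2 at 22 °C, and 108 or 105 without B or C of gemin2 at 24 h, in place of 164. Without the host gene's reads in the model 2559 introns rose and 1216 fell in gemin2, with a median log2 change over all introns of 0.319 in place of 0.198, and 801 bins rose and 731 fell, while in WT 2740 introns passed in place of 378 and 1397 bins in place of 130.

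The interaction asks whether the cold response itself differed between the genotypes. After 1 h it did so past the threshold for 21 genes, 9 with a higher and 12 with a lower change in gemin2. The clock genes LNK1 and LNK2 (AT3G54500), the latter overlapped by another gene, fell in WT, and their change in gemin2 was higher (interaction 0.91 ± 0.16 and 0.86 ± 0.14), while CO rose less in gemin2 (-1.55 ± 0.26, adjusted p = 0.0124). All 3 lost their call without library A of WT at 1 h, LNK1 also without any single library of gemin2 at 22 °C or without C of either genotype at 1 h, LNK2 without B or C of WT at 22 °C, and CO without C of either genotype at 22 °C. DFL2 (AT4G03400) had the smallest adjusted p (-1.64 ± 0.14, adjusted p = 1.80e-06), ahead of ATOFP16 (AT2G32100) (-1.55 ± 0.20) and AT1G75960 (-1.39 ± 0.18). AT1G70420 (1.76 ± 0.25) and ATGSTF6 (AT1G02930) (1.23 ± 0.19) had higher changes in gemin2. Of the fixed lists none passed as a set with camera. Of the introns 6 passed, all higher: those in GRP7 (1.01 ± 0.17), intron I001 of KRP6 (AT3G19150, chromosome 3, 6616692 to 6616933) (2.97 ± 0.58), intron I001 of CCL (AT3G26740, chromosome 3, 9828065 to 9828147) (1.71 ± 0.34), intron I014 of STY46 (AT4G38470, chromosome 4, 18003167 to 18003239) (3.30 ± 0.67), intron I001 of AT4G23670 (chromosome 4, 12333115 to 12333469) (1.91 ± 0.36) and, outside the naming rule for its low count and so chosen after its values were seen, AT2G42750:I005 (4.01). The first 5 each lost their call without some library. Intron I002 of GRP7 went from 6.14% to 4.16% in WT and from 6.75% to 9.19% in gemin2. No bin passed with edgeR, which gave 360 bins at an unadjusted p under 0.05, and DESeq2 called 15. These small counts moved with single libraries: the genes ran from 7 without library A of WT at 1 h to 117 without library A of gemin2 at 1 h, where 31 were higher and 86 lower, and the introns from 1 without that library of WT to 21 without that of gemin2. With DESeq2 102 genes were higher and 82 lower, and without rRNA genes, a setting chosen after the data were seen, 20 were higher and 12 lower. A replicate block on the letters moved the number of genes most, to many more than 21, and also gave more introns, as reported with the dependence on processing.

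After 24 h the cold response differed for 3052 genes, 1627 higher and 1425 lower in gemin2. LHY, whose WT value is given here after it was seen, changed by -0.44 ± 0.11 in WT and by 2.13 ± 0.12 in gemin2 (interaction 2.57 ± 0.16, adjusted p = 1.61e-09). CCA1 (1.77 ± 0.17) and RVE8 (2.05 ± 0.19) moved with it. GRP7, which rose in both genotypes, rose less in gemin2 (-1.31 ± 0.18), and the heat shock genes HSP90.1 (1.33 ± 0.17) and HSP70 (1.17 ± 0.18) fell less.

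Of the 22 clock genes 7 had higher and 7 lower changes in gemin2 (9 and 7 adjusted over the list alone). The lower ones, named here after their values were seen, were PRR7 (-1.40 ± 0.15), PRR5 (-1.33 ± 0.21), FKF1 (AT1G68050) (-1.86 ± 0.37), GI (-0.97 ± 0.16), LUX (AT3G46640) (-0.90 ± 0.24), CHE (AT5G08330) (-0.70 ± 0.19) and TOC1 (AT5G61380) (-0.62 ± 0.14). LUX and CHE lost their call without library B of WT at 22 °C or C of WT at 24 h, LUX also without B or C of gemin2 at 24 h and CHE without C of gemin2 at 22 °C. Of 11 ABA response genes 6 were higher (9 adjusted over the list alone), with HAB1 at 1.253 ± 0.14 and LEA4-5 (AT5G06760) at 2.01 ± 0.47. Of 9 heat shock genes 3 were higher by both counts, and of 33 snRNP genes 4 by both counts, with STA1 at 0.76 ± 0.14. These 3 lists passed with the preset correlation (adjusted p = 3.23e-05, 0.0339 and 0.0339) and not with an estimated one (adjusted p = 0.472, 0.472 and 0.322). Of the cold list 3 were higher and 1 lower by both counts, with ADH1 at 1.85 ± 0.37 and LTI30 at 0.79 ± 0.19.

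The smallest adjusted p among higher changes belonged to the glucosyltransferase genes UGT73C6 (AT2G36790) (3.67 ± 0.22), which overlaps AT2G36792, and DOGT1 (AT2G36800) (2.67 ± 0.17), whose sequences are similar, and to EMB86 (AT5G22800) (1.75 ± 0.11). Among lower changes they were those of AT1G75960 (-2.91 ± 0.20), the starch phosphorylase gene PHS1 (AT3G29320) (-1.67 ± 0.12, overlapped by another gene), AT5G23240 (-2.57 ± 0.18, likewise overlapped), EMB2729 (AT3G20440) (-1.95 ± 0.15) and PORB (AT4G27440), an enzyme of chlorophyll synthesis (-2.09 ± 0.17). CYCB1;1 (1.60 ± 0.26), FUL (AT5G60910) (3.34 ± 0.70), ICS1 (1.00 ± 0.22), TT8 (1.49 ± 0.44) and RBCS2B (1.05 ± 0.26) had higher changes in gemin2, and FMO1 a lower one (-2.65 ± 0.51). TT8 lost its call without any 1 of 8 libraries, among them each of gemin2 at 22 °C.

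Of the introns 63 passed, 58 with a higher change in gemin2. Intron I001 of PGP4 (AT2G47000, chromosome 2, 19310362 to 19310456), a transporter gene, went from 1.096% to 0.239% in WT and from 0.688% to 3.67% in gemin2 (4.43 ± 0.55). Intron I006 of UAP56a (AT5G11170, chromosome 5, 3554940 to 3555623), in a gene of an RNA helicase, changed by 1.62 ± 0.24, intron I001 of AGT1 (AT2G13360, chromosome 2, 5539555 to 5539632) by 3.33 ± 0.44, intron I016 of AT5G18190 (chromosome 5, 6013784 to 6014398) by 2.15 ± 0.37 and intron I009 of RS40 by 3.91 ± 0.81. The 5 lower introns were those in AT1G13350 (-2.33 ± 0.45), intron I003 of RbcX1 (AT4G04330, chromosome 4, 2117055 to 2118002) (-1.60 ± 0.32), intron I005 of SPDS2 (AT1G70310, chromosome 1, 26486505 to 26486787) (-2.55 ± 0.58), intron I006 of CSP41B (AT1G09340, chromosome 1, 3016877 to 3017044) (-1.64 ± 0.40) and, named after its values were seen, AT5G20070:I001 of ATNUDT19 (-4.49). Without library B of WT at 22 °C 21 introns passed, and without the other libraries between 26 and 78. The 3 bins past the threshold were bin E003 of IMPA-2 (AT4G16143, chromosome 4, 9134325 to 9134447), a retained intron (1.80 ± 0.32), bin E006 of UBQ10 (AT4G05320, chromosome 4, 2718543 to 2718558) (1.67 ± 0.32) and bin E006 of AT5G47455 (chromosome 5, 19251658 to 19251704), a skipped exon (-2.41 ± 0.45), and with only these 4 groups in edgeR's fit none passed. Each of the 3, the RS40 intron and 4 of the lower introns lost their call without some library, and that in AT1G13350 without the host gene's reads in the model. Without the host gene's reads in the model 270 introns were higher and 64 lower.

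Reads in all introns together made up a larger share of gene counts in gemin2 than in WT in the cold groups. The shares were 1.96 ± 0.0408% and 1.86 ± 0.252% at 22 °C in WT and gemin2, 2.06 ± 0.0699% and 2.37 ± 0.133% after 1 h, and 2.16 ± 0.0818% and 2.56 ± 0.167% after 24 h. The mean difference over the 3 conditions was 0.207 percentage points (exact permutation test within conditions, two-sided p = 0.031). At 22 °C the library rich in rRNA lowers the gemin2 mean. With rRNA genes out of the total, a setting chosen after the data were seen, the shares at 22 °C were 1.97 ± 0.0398% and 2.05 ± 0.0537% and the mean difference 0.273 points (exact permutation p = 0.00025, the smallest that the 8000 permutations can give). Over the tested introns alone the difference was 0.0527 points (exact permutation test, p = 0.276). The p of the main test was over 0.05 without library A of WT at 22 °C (exact permutation p = 0.0525), A or B of gemin2 at 22 °C (0.07 and 0.0792) or A of WT at 24 h (0.0518).

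Side by side, the cold responses of the genotypes ran in the same direction for most of the genes called in both. After 24 h 9598 genes passed in both genotypes and 97.8% of them changed the same way, 4689 up and 4696 down against 1766 and 1856 for independent lists. The correlation across genes was 0.797 with a slope of 0.844 for gemin2 on WT. After 1 h 1537 genes passed in both and 99.7% changed the same way, with a correlation of 0.605 and a slope of 0.466. Across introns the correlations were 0.342 at 24 h and 0.390 at 1 h. Genes and introns are not independent replicates, so these values carry no p. The gemin2 effect at 22 °C and the WT response to 24 h of cold share the WT libraries at 22 °C, which alone gives a correlation. Across introns it was 0.529 with a covariance of 0.395, against 0.606 and 0.2 in simulated groups with no change, and across genes 0.292 and 0.208 against 0.561 and 0.0541. Of the introns called in both, 51 were higher in both against 9.25 for independent lists, and 14 lower in both against 1.47. The numbers for independent lists leave out the shared libraries, so part of the excess may come from them.

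The authors' deposited table of genes at 22 °C lists 907 higher and 1082 lower genes, with a log2 change of at least 0.585 in size. The fit here gave all 1989 the same direction and called 1739 of them. For introns at 22 °C the authors' deposited table lists 643 higher and 365 lower, up to an FDR of 0.105 against 0.05 here, of which 611 met the filter here, 608 in the same direction and 329 called. For alternative splicing bins at 22 °C the authors' deposited table lists 174 higher and 124 lower, up to an FDR of 0.104, of which 241 met the filter here, all in the same direction and 85 called. In the other comparisons all genes tested here had the same direction, and 85.09% to 98.52% were called. The headers of the authors' gene tables for the genotypes after 1 h and 24 h name WT over gemin2. Their values, taken as they stand, had the direction of gemin2 over WT in the fit here, so header and values disagree. For introns 93.58% to 99.88% had the same direction and 22.51% to 60.69% were called. For bins these ranges were 94.16% to 100% and 14.96% to 46.98%.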

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

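The tests of other splits of the libraries, of the clock genes and of the shared WT libraries were chosen after the results were seen. The results below stood out because the cold response differed between the genotypes by the interaction test, and each value is the log2 interaction.

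After 1 h the interaction passed for 21 genes and 6 introns, and for many more of the genes with a replicate block on the letters or with DESeq2. It was 0.91 for LNK1, 0.86 for LNK2, -1.55 for CO, -1.64 for DFL2, -1.55 for ATOFP16, -1.39 for AT1G75960, 1.76 for AT1G70420 and 1.23 for ATGSTF6. Of these, LNK1, LNK2 and CO lost their call without library A of WT at 1 h, and without some others. The introns had 1.01 in GRP7, 2.97 in KRP6, 1.71 in CCL, 3.30 in STY46, 1.91 in AT4G23670 and 4.01 in AT2G42750. The first 5 of these introns each lost their call without some library.

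After 24 h it passed for 3052 genes, 63 introns and 3 bins. Among clock genes it was 2.57 for LHY, 1.77 for CCA1, 2.05 for RVE8, -1.40 for PRR7, -1.33 for PRR5, -1.86 for FKF1, -0.97 for GI, -0.90 for LUX, -0.70 for CHE and -0.62 for TOC1. LUX and CHE lost their call without library B of WT at 22 °C or C of WT at 24 h, and without some others. The ABA response, heat shock and snRNP lists had medians of 0.97, 0.20 and 0.26. Their members had 1.253 for HAB1, 2.01 for LEA4-5, 1.33 for HSP90.1, 1.17 for HSP70 and 0.76 for STA1. Cold genes had 1.85 for ADH1 and 0.79 for LTI30, and GRP7 had -1.31. Further values were 3.67 for UGT73C6, 2.67 for DOGT1, 1.75 for EMB86, 1.60 for CYCB1;1, 3.34 for FUL, 1.00 for ICS1, 1.49 for TT8, which lost its call without any 1 of 8 libraries, and 1.05 for RBCS2B. Lower values were -2.91 for AT1G75960, -1.67 for PHS1, -2.57 for AT5G23240, -1.95 for EMB2729, -2.09 for PORB and -2.65 for FMO1. Introns had 4.43 in PGP4, 1.62 in UAP56a, 3.33 in AGT1, 2.15 in AT5G18190, 3.91 in RS40, -2.33 in AT1G13350, -1.60 in RbcX1, -2.55 in SPDS2, -1.64 in CSP41B and -4.49 in ATNUDT19, and the last 6 of these lost their call in some setting. The bins had 1.80 in IMPA-2, 1.67 in UBQ10 and -2.41 in AT5G47455, and each lost its call without some library.

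The clock genes' interaction at 24 h held 14 calls. Without the library rich in rRNA, C of gemin2 at 22 °C, 13 of them stayed called with the same sign, which argues against that library as the source. The 8 morning genes had a median of 0.802 and the 10 day or evening genes one of -0.80, a difference of 1.60. A different clock phase, or a different hour of harvest, could give such a pattern. The labels give no harvest hours, so these cannot be told apart, and a genotype effect on the clock stays open as untested. This limit holds for the clock genes in the other comparisons too. For gemin2 against WT the morning and evening medians were -0.411 and 0.781 at 22 °C and -0.548 and 0.616 at 1 h. For cold 1 h they were -0.0782 and 0.75 in WT and 0.295 and 0.316 in gemin2.

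For the introns higher in gemin2 at 22 °C, host genes' log2 changes differed by -0.0176 in the median from those of introns not called, which argues against fewer gene reads as the source. Weak 5' splice sites stay open. At 22 °C the median score was higher in called introns, at 7.305 against 7.108, the direction opposite to weak sites. That difference of 0.197 lay within its spread (permutation test, two-sided p = 0.159). For introns higher after 1 h and 24 h the median score differed by -0.0941 and -0.125 (permutation tests, two-sided p = 0.251 and 0.0595). Introns share genes and libraries, so these p-values do not measure the spread between libraries. The excess of intron reads in the top quartile of host gene level was 2.49 times that in the bottom quartile by the means the test named, and 1.78 by medians, which were computed first and lie within the limit of 2 set for this source, so reads from genomic DNA or unprocessed RNA could add to it. Introns not called had an excess of -0.00224 times that of called ones, a test prompted by that outcome. Called introns were selected for their excess, which inflates their side of this ratio. From the bottom quartile of host gene level up, those not called had a median excess of 0.00864, 0.106, 0.096 and -0.254. Called introns had 3.665, 4.522, 4.827 and 6.511. Counts in rRNA genes, 22.5% of library C of gemin2 at 22 °C, would lower the gemin2 values if the library totals hold them. No excess without rRNA genes is given, so DNA spread over all introns stays open. U12-type introns were 2 of 380, a ratio of 0.805 to those not called, too few to tell, and a splicing effect of the mutation stays open.

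The gemin2 effect at 22 °C moved with the WT response to 24 h of cold across introns. The covariance was 1.98 times that of simulated unchanged groups. With 1 WT library in one comparison and the other 2 in the other, in 6 ways, it ran from 0.171 to 0.254, with a mean 1.101 times the excess of 0.195 over the simulated value, which argues against sampling noise of the shared libraries as the whole source. Between the gemin2 effect after 1 h and the same WT response, the covariance came to 0.0742 of that excess. A shift of the whole WT group at 22 °C, technical or biological, could give such values and stays open, as does an effect of the mutation that matches that of cold, because that group enters both comparisons.

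Other splits of the libraries were counted. For each of the 21 comparisons of 3 against 3 libraries, 1 of the 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. Every other split mixes the real groups and puts their difference into the spread within groups. That lowers its count beforehand, so the counts below do not exclude chance. In fits of these 6 libraries alone the real split called, for genes, 4869, 7262 and 7419 for gemin2 against WT at 22 °C, 1 h and 24 h, 5784 and 11229 for cold in WT and 1796 and 12900 for cold in gemin2, against at most 0 for the others. For introns these were 428, 1521, 1519, 470, 177, 901 and 1358, with highest others of 1, 3, 1, 2, 1, 2 and 1. For bins they were 138, 286, 190, 249, 54, 21 and 176, with highest others of 0, 0, 0, 2, 0, 1 and 0.

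For the interactions 100 splits of the 12 libraries were drawn, in fits of their 4 groups alone. As many calls as the real split came in 7 for genes at 1 h (real 52, highest other 9646), 8 at 24 h (2633 and 9165), 9 for introns at 1 h (12 and 1580), 12 at 24 h (45 and 1547), 12 for bins at 1 h (1 and 514) and 100 at 24 h (0 and 380). So chance is not excluded by this count. The splits that call several times the real count exchange unequal numbers of libraries in the conditions, which turns the genotype difference into an interaction, a structure of the samples. Among 82 splits with equal exchange, 1 gave as many for genes at 1 h and 1 at 24 h (highest other 0), 1 for introns at 1 h and 1 at 24 h (highest other 1), 4 for bins at 1 h (highest other 1) and 82 at 24 h (highest other 0). Equal exchange puts the genotype difference into the spread within groups, which lowers these counts beforehand, so they do not exclude chance.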

How the results depend on the processing

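Of 261 named features, each counted per comparison, 226 kept their sign in every setting run and, where called, their call. In some setting 31 lost a call with their sign unchanged. Further, 5 changed sign in some setting, 1 of which is also among the 31. Those that lost a call with their sign unchanged were CO, LNK1 and LNK2 in the 1 h interaction, CHE, LUX and TT8 in that at 24 h, PSBA, PSBD, UF3GT and the introns named in LSM1B, GEMIN2 and AT5G41750 at 22 °C, introns I004, I005 and I007 of CCA1 and I004 of PRR7 for gemin2 against WT at 24 h, bin E021 of AGO1 in WT at 24 h, 5 introns of the 1 h interaction, 6 introns of that at 24 h and its 3 bins. The interaction of GEMIN2 at 1 h, which passed nowhere, ran from -0.162 without library B of gemin2 at 22 °C to 0.02225 without its library C. Without the host gene offset, intron I002 of GRP7 had 1.47 in WT at 24 h, intron I004 of CCA1 had 0.11 in gemin2 at 24 h, and intron I003 of GEMIN2 had -0.4997 and -0.06339 for gemin2 against WT at 22 °C and 24 h, which follows from leaving out the gene's own change. In that setting the CCA1 intron lost its call (edgeR adjusted p = 0.818), and so did the GEMIN2 intron at 22 °C and 24 h (edgeR adjusted p = 0.516 and 0.94).

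With a replicate block on the letters, 247 genes (21 without it) and 15 introns (6) passed in the 1 h interaction. For bins 174, 541 and 349 passed for gemin2 against WT at 22 °C, 1 h and 24 h, 355 and 202 for cold 1 h and 24 h in WT, and 6 in the 24 h interaction, and no other count moved by over 1.5 times. Same-letter libraries correlated with a median of 0.0622 and a lowest value of -0.115, with 11 of 45 pairs over 0.1, against a median of -0.0499 and 7 of 90 for other letters. Not every same-letter pair was over 0.1 and no label ties a letter to a batch, so the main fits do not pair the libraries. Yet 12 of 18 libraries correlated best with their own letter, a hint of pairing from the data. In every group but WT at 1 h, library A lay lowest on principal component 5 (3.125% of the variance). In gemin2 at 24 h it stood at -31.46, against 12.92 and 10.62 for B and C. An effect shared by letter is therefore not excluded, and the main fits leave it out. The cause of the moves in counts was not tested.

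An absolute log2 change of at least 1 left, by construction, 959, 1431 and 1951 genes for gemin2 against WT at 22 °C, 1 h and 24 h, 1163 and 4746 for cold 1 h and 24 h in WT, 683 and 5472 in gemin2, and 10 and 909 in the interactions, and 161, 73 and 67 bins for gemin2 against WT at 1 h and cold 1 h and 24 h in WT. For genes in the 1 h interaction DESeq2 called 184, no filter 38, the fit without rRNA genes, added after the data were seen, 32, and the fit of these groups only 52. Without the host gene offset 817 introns passed at 22 °C, 1004 and 2740 for cold in WT, 1065 and 3775 in gemin2 and 334 in the 24 h interaction, and 378, 572 and 802 bins for gemin2 against WT, 393 and 1397 for cold in WT, 138 and 1532 in gemin2 and 181 in the 24 h interaction. A mean of 3 counts gave 2994 introns for gemin2 against WT at 24 h, 1951 for cold 24 h in gemin2 and 11 in the 1 h interaction, where more are tested. With only the compared groups, 177 introns and 54 bins passed for cold 24 h in WT, 12 introns and 1 bin in the 1 h interaction, and edgeR gave 0 bins in the 24 h interaction. DESeq2 called 38 and 123 introns and 15 and 14 bins in the 1 h and 24 h interactions. Camera passed 47 lists over all contrasts and 13 with an estimated correlation. These were 4 and 0, 6 and 0, and 8 and 0 for gemin2 against WT at 22 °C, 1 h and 24 h, 5 and 3, and 9 and 3 for cold 1 h and 24 h in WT, 5 and 4, and 7 and 3 for cold 1 h and 24 h in gemin2, 0 and 0 in the 1 h interaction, and 3 and 0 in the 24 h interaction. The intron share difference over tested introns was 0.0527 points (exact permutation p = 0.276). The cause was not tested where none is given.

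Leaving out 1 library each gave 3611 to 5457 genes for cold 1 h in WT (3611 and 3623 without A and B of WT at 1 h) and 7 to 117 in the 1 h interaction (53, 11 and 10 without A, B and C of WT at 22 °C, 10 without C of gemin2 at 22 °C or at 1 h, 7 without A of WT at 1 h and 117 without A of gemin2 at 1 h). For introns it gave 283 to 512 for cold 1 h in WT (283 without B of WT at 1 h, 357 and 375 without B and C of WT at 22 °C), 218 to 318 for cold 24 h in WT (218 without B of WT at 24 h), 418 to 539 for cold 1 h in gemin2 (426, 418 and 445 without A, B and C of gemin2 at 22 °C), 1 to 21 in the 1 h interaction and 21 to 78 in the 24 h interaction. In the 1 h interaction these were 2 and 11 without A and C of WT at 22 °C, 1, 3 and 2 without A, B and C of gemin2 at 22 °C, 1, 2 and 11 without A, B and C of WT at 1 h, and 21 and 2 without A and C of gemin2 at 1 h. In the 24 h interaction they were 21 without B of WT at 22 °C, 36 and 35 without B and C of gemin2 at 22 °C, 35 and 26 without A and C of WT at 24 h, and 38 and 27 without B and C of gemin2 at 24 h. For bins the ranges were 64 to 94, 120 to 574 and 147 to 397 for gemin2 against WT (64 and 69 without A and C of gemin2 at 22 °C, 574, 120 and 144 without A, B and C of gemin2 at 1 h, 163 and 127 without A and B of WT at 1 h, 397, 147 and 151 without A, B and C of gemin2 at 24 h), 31 to 228 and 77 to 98 for cold in WT (31 and 54 without B and A of WT at 1 h, 79 and 67 without B and C of WT at 22 °C for 1 h, 78 and 81 without these and 85 and 77 without B and C of WT at 24 h for 24 h), 11 to 19 and 92 to 126 for cold in gemin2 (13, 12 and 14 without A, B and C of gemin2 at 22 °C and 11 without B of gemin2 at 1 h for 1 h, 92 and 105 without A and C of gemin2 at 22 °C, 108 and 105 without B and C of gemin2 at 24 h for 24 h), and 0 to 19 and 0 to 7 in the interactions. For 1 h these were 2 without C of WT at 22 °C, 7 without C of WT at 1 h and 19 without A of gemin2 at 1 h. For 24 h they were 0 and 6 without B and C of WT at 22 °C, 1 without B of gemin2 at 22 °C, 1, 0 and 5 without A, B and C of WT at 24 h, and 7 and 0 without A and B of gemin2 at 24 h. The intron share difference ran from 0.1795 to 0.2552 points. Across introns the correlation of the cold responses ran from 0.304 to 0.342 and that of the gemin2 effect with WT cold from 0.437 to 0.676. Counts fall in part because fewer libraries are tested.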

Other observations

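The tests of intron length and GC content and of U12-type introns after 24 h were chosen after the called introns were seen. Of the 10 genes of cell division and meristems, 1 rose and 6 fell in WT after 24 h at 10 °C and 2 rose and 6 fell in gemin2, over all genes and adjusted over the list alone, and the set passed in neither (adjusted p = 0.291 and 0.625). Of 4 floral organ genes 2 were measured, and 1 was higher in gemin2 after 1 h (2 adjusted over the list alone), with an adjusted p of the list of 0.138. Of 7 seed maturation genes 4 were measured, of which 2 fell in WT and 3 in gemin2 after 24 h by both counts (adjusted p of the list 0.279 and 0.297). Of 5 reference genes edgeR called none between the genotypes at 22 °C, over all genes or the list alone, with a median log2 change of -0.11, and 2 were higher in gemin2 after 24 h.

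Introns with more reads in gemin2 at 22 °C had a median length of 103.5 bp against 127 bp for introns not called (permutation test, two-sided p = 0.0312), while those higher after 1 h and 24 h were longer, at 150 bp each against 125 and 124 bp (not tested). At 22 °C they had a median GC content of 34.7% against 33.4% (permutation test, two-sided p = 1e-05, the smallest that 100000 permutations can give), and after 1 h and 24 h it was 34.1% and 34.7% against 33.3% each (not tested). Among introns higher in gemin2 after 24 h, 3 of 1435 had a U12-type 5' site against 54 of 7753 not called (Fisher's exact test, two-sided p = 0.0272, 1 of 6 such tests and not corrected for their number). The tests of length, GC content and U12-type sites take introns as separate units. Introns share genes and libraries, so these p-values do not measure the spread between libraries.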
